A study of Homo sapiens with 18 samples.

How the data were processed

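RNA of HEK 293T cells of 3 genotypes was measured after 0, 1 or 2 h of labelling with 100 µM s4U, in 18 libraries (9 groups of genotype and time, 2 replicates each). Per the labels' protocols, total RNA was treated with iodoacetamide and made into QuantSeq 3′ libraries. The labels name the second knockout CTU2, while the protocol text names a CTU1 knockout, and the labels' name is used here without deciding between them. Per the submitters' processing notes, the reads were placed on hg38, and the series design text names GRAND-SLAM, which estimates how much of each transcript is new from its T to C conversions. The aligner, the annotation and the program versions are not given in the sources used here.

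The deposited table holds read counts per gene, region (exonic or intronic) and library, with counts of conversions, of covered T positions and of reads with several conversions, whole numbers without normalization. The authors also deposited a new-to-total ratio as a fraction, as the most probable value and as the posterior mean, for labelled libraries. The deposited parameters of its beta posterior are scores without a unit. A length in bases is given for each gene. The table held 27461 genes with exonic and 18421 with intronic entries and 30 entries for ERCC spike-in sequences, which took 0 to 7 reads per library and were left out. Of the gene identifiers 27339 were found in the symbol table and 5616 genes had no symbol, and these were counted but not named. Coordinates came from a RefSeq gene table of assembly GRCh38.p14, the patched release of the same build, for symbols found once. Genes were treated as sharing reads where a pair had counts within 10% of each other in every library and a mean of at least 10 reads, which gave 152 pairs, and near-identical copies were named as uncertain as well.

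Exonic reads came to 3482642 to 6400584 per library, with 17360 to 19017 genes detected and 8.28 to 19.5% of reads in introns. The first 3 principal components held 25.4, 14.9 and 11.6% of the variance. CTU2 2 h replicate 1 lay farthest out on component 1 (0.79). ELP1 0 h replicate 2 had the lowest value on component 3 (-0.42), although CTU2 1 h replicate 2 lay farther out there (0.48). CTU2 2 h replicate 1 and ELP1 0 h replicate 2 are called the 2 libraries that stand apart below. Differences between the replicates of a group exceeded sampling noise by factors of 4.73 (WT 1 h) to 26.7 (CTU2 2 h) as chi-square per degree of freedom, and the biological coefficient of variation was 21.2%. The numbers 1 and 2 did not pair libraries across groups, since over 36 pairs of groups the correlation of replicate differences ran from -0.28 to 0.36 with a median of -0.03, with 10 above 0.1 and 9 below -0.1. No replicate block was therefore used except as an alternative.

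Abundance was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr with a minimum count of 10 over the 9 groups (13514 genes left), a quasi-likelihood F test and Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. Genotypes were compared over 6 libraries each with labelling time as a factor, and labelling times within a genotype with a mean per group and the spread shared over all groups. The standard error of a log2 fold change was taken as its size over the square root of F. A response that differed between genotypes was tested as an interaction. Turnover was computed as k = -ln(1 - ratio)/hours from the deposited most probable ratio limited to 0.01 to 0.99, centred on the median gene of each library, and tested on log2 k with limma 3.58.1 and a trend on mean reads over the 12 labelled libraries, 4 per genotype. It used the 6578 genes with a mean of at least 100 reads and a ratio in every labelled library. New RNA was log2 of the ratio times TMM-scaled CPM plus 1, tested the same way. Half-lives are ln(2)/k, assume a steady state and hold no correction for cell growth. Library medians of log2 k before centring and conversion rates were compared by exact two-sided permutation of 4 against 4 libraries, and again with libraries exchanged only within a labelling time. Intronic reads of 9448 genes were tested as abundance was.

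There were 26 gene lists, of which those with at least 5 tested members were used (25 for abundance, 22 for turnover and new RNA). Each was tested with camera from limma at an inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison, and members were counted as called over all genes and adjusted over the list alone. Before the data were examined, the groups, comparisons, tests, thresholds, gene lists, rule for named genes and most alternatives were fixed. The rule named ELP1 and CTU2 first. It then took, per knockout against WT, the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM in a genotype and the same sign at each labelling time. It took 5 and 5 for the knockouts against each other, for genes called in both and for each genotype at 2 h of labelling, and up to 4 members of each list by adjusted p. For half-lives it took 3 members by read count of each of 3 lists. Where a group had 1 to 3 reads the ratio of reads scaled to library size is given with its exact 95% counting interval, and where it had none the limit of 3 reads over the group.

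The overlap of the knockouts was set against 20 draws of unchanged groups simulated with the same WT libraries, against independent lists, and against fits in which the WT libraries were divided by replicate number. Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a replicate block, fewer libraries or genotypes, a minimum change, leaving out each library in turn, and for turnover another estimate, minimum read count, scale, weighting or centring. Added after the data were seen were the permutation within labelling times, and fits without the 2 libraries that stand apart, with 0 h and 1 h libraries only, and with the trend on transcript length of each library removed by an offset (a natural spline with 5 degrees of freedom). A library left alone in its group was assumed to vary like the others. Relations to codon content were planned but not computed, because no coding sequences were at hand.

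The tests of abundance and turnover were run on simulated counts with 200 changed genes, the test of new RNA with 164, and the list test with 2 lists moved. For the CTU2 knockout against WT edgeR recovered 7.46, 62.7 and 97.0% of genes changed by 0.5, 1 and 2 on the log2 scale among 13514, with 7.5% of calls false, and DESeq2 8.96, 68.7 and 97.0% with 14.7% false. For 2 h against 0 h in the CTU2 knockout edgeR recovered none, 14.9% and 71.2%. For turnover limma recovered none, 7.46% and 63.6% among 6578 genes, and for new RNA 42 changed genes with 0 false calls. Both lists, moved by 0.5, were called by camera among 23, and no other.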

Results

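Transcript abundance and newly made RNA were measured in HEK 293T cells, a human embryonic kidney line, that were unmodified (WT), labelled as ELP1 knockout or labelled as CTU2 knockout. ELP1 is the scaffold of Elongator, the complex that starts the mcm5 modification of the wobble uridine (U34) of certain tRNAs, and CTU2 works with CTU1 in adding the 2-thio group of mcm5s2U34. Cells were exposed to 100 µM 4-thiouridine (s4U), a uridine analogue built into new RNA, for 0, 1 or 2 h, and alkylated s4U is read as a T to C conversion in 3′ end sequencing. There were 18 libraries in 9 groups of genotype and labelling time, with 2 replicates in each group and 6 libraries per genotype. Reads assigned to exons numbered 3482642 to 6400584 per library. The precision of each value was set by these depths and by the spread between replicates, and intervals and limits from read counts cover counting error only. Values per genotype are mean CPM, reads scaled to library size, with the SD over 6 libraries, and log2 fold changes carry the standard error of the edgeR fit. Adjusted p-values measure the spread between these libraries, which may be technical. The labels do not say how many clones each genotype had. Genome positions are on hg38.

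CTU2 mRNA (ENSG00000174177, chromosome 16, 88706503 to 88715396) was lower in every library labelled CTU2 knockout than in any other library. In that genotype CTU2 stood at 5.14 and 6.93 CPM at 0 h, 6.51 and 2.97 CPM at 1 h, and 8.87 and 6.84 CPM at 2 h. In WT it stood at 17.5 and 29.7 CPM at 0 h, 27.0 and 30.1 CPM at 1 h, and 27.6 and 17.9 CPM at 2 h. The ELP1 knockout held 19.0 and 12.1 CPM of CTU2 at 0 h, 18.1 and 19.8 CPM at 1 h, and 18.05 and 18.1 CPM at 2 h. The CTU2 knockout mean of 6.21 ± 1.99 CPM differed from the WT mean of 24.96 ± 5.74 CPM by a log2 fold change of -2.01 ± 0.22 (edgeR adjusted p = 1.34e-06). With 0 h libraries only it was -1.97 and the call was lost (adjusted p = 0.0603), as was that of the ELP1 against the CTU2 knockout (adjusted p = 0.229). The ELP1 knockout mean of 17.5 ± 2.77 CPM differed from WT by -0.51 ± 0.20 (adjusted p = 0.111). ELP1 mRNA (ENSG00000070061, chromosome 9, 108867517 to 108934124) was present in all libraries. In the ELP1 knockout it stood at 61.6 and 42.9 CPM at 0 h, 43.0 and 48.3 CPM at 1 h, and 53.6 and 53.8 CPM at 2 h. In WT it stood at 57.5 and 67.4 CPM at 0 h, 63.9 and 66.1 CPM at 1 h, and 63.4 and 61.0 CPM at 2 h. The CTU2 knockout held 56.7 and 69.7 CPM of ELP1 at 0 h, 61.4 and 71.1 CPM at 1 h, and 41.3 and 60.1 CPM at 2 h. The ELP1 difference was -0.32 ± 0.14 in the ELP1 knockout (adjusted p = 0.151) and -0.08 ± 0.14 in the CTU2 knockout (adjusted p = 0.803). The edited position is not stated and the reads come from the 3′ end, so the level of a 3′ tag checks no label by itself. Genotype names below are those of the labels.

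**Figure D1:**
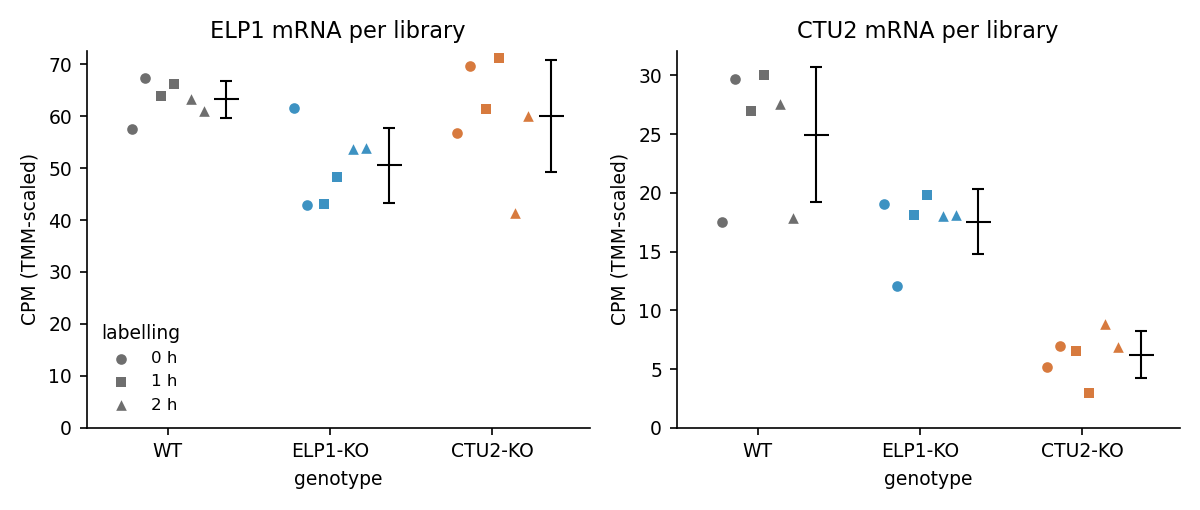
CTU2 and ELP1 mRNA in CPM in each of the 18 libraries, by genotype, with the marker giving the labelling time and the bar the mean and SD of 6 libraries. CTU2 averaged 6.21 CPM in the CTU2 knockout and 24.96 CPM in WT, while ELP1 averaged 50.5 CPM in the ELP1 knockout and 63.2 CPM in WT.

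The comparison of the ELP1 knockout with WT asks how mRNA levels differ in cells labelled as lacking the first U34 modification step, which was not measured. ELP1 knockout cells expressed several transcripts that were close to absent in WT. BMP2, a secreted growth factor of the TGF-beta family (ENSG00000125845, chromosome 20, 6767686 to 6780246), reached 26.3 ± 3.19 CPM against 0.789 ± 0.421 CPM in WT. PCSK2, a prohormone convertase, reached 22.1 ± 4.54 CPM against 0.261 ± 0.323 CPM. INSM1, a transcription factor of neuroendocrine cells, reached 78.2 ± 35.8 CPM against 3.75 ± 1.69 CPM. In the other direction UNCX, a homeobox gene (ENSG00000164853, chromosome 7, 1232872 to 1237326), fell from 30.2 ± 10.7 to 0.576 ± 0.4656 CPM. CCND1, which encodes cyclin D1, fell from 81.1 ± 11.7 to 29.3 ± 3.01 CPM. These changes came to 5.01 ± 0.30 for BMP2 (adjusted p = 1.70e-10), 6.38 ± 0.41 for PCSK2 (1.90e-10), 4.38 ± 0.33 for INSM1 (2.53e-09), -5.75 ± 0.37 for UNCX (1.90e-10) and -1.47 ± 0.14 for CCND1 (1.90e-07). SOX11, a neural transcription factor, had 536 reads over the 6 ELP1 knockout libraries and 1 read over the WT libraries, a ratio of 487 after scaling to library size with a 95% counting interval of 87 to 19300. The other largest rises were in PTN (5.98), SCG3 (3.98), CDH7 (3.23), MAL2 (2.41), BASP1 (2.38) and EMILIN2 (2.29), with adjusted p from 2.31e-09 to 4.45e-07. The other largest falls were in FOXF1 (-4.05), the long noncoding RNA FIRRE (-2.04), COL4A5 (-1.75), NOTCH1 (-1.73), PPP2R2C (-1.49), LRRC3 (-1.47), GPSM1 (-1.45) and MAP7D2 (-1.40), with adjusted p from 1.89e-09 to 0.00119. In all, 675 genes were higher and 640 lower among 13514 tested, of which 379 changed by at least 1 on the log2 scale, 291 higher and 88 lower. The called genes had a median absolute change of 0.74.

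Among the gene lists fixed in advance, cholesterol biosynthesis fell together in the ELP1 knockout. Of its 23 tested members 9 were lower and none higher, and 12 were lower when adjusted over the list alone. The median change was -0.41 (camera adjusted p = 2.15e-07; adjusted p = 0.00222 with an estimated correlation). FDFT1, which makes squalene, changed by -0.84 ± 0.14, CYP51A1 by -0.70 ± 0.14, SQLE by -0.58 ± 0.11 and IDI1 by -0.94 ± 0.19. Heat shock and cytosolic chaperones also fell, with 4 of 24 members lower, 7 lower adjusted over the list alone, and a median of -0.29 (adjusted p = 6.21e-06; adjusted p = 0.0191 with an estimated correlation). HSPA1B changed by -0.72 ± 0.15 and the chaperonin subunit CCT2 by -0.45 ± 0.12. Epithelial markers rose, with 4 of 8 higher and 4 adjusted over the list alone, and a median of 0.61 (adjusted p = 0.00216; adjusted p = 0.0191 with an estimated correlation). Of these, CDH2 encodes N-cadherin, which neural and mesenchymal cells also express, and changed by 0.79 ± 0.15. The other called members were at low levels. The tight junction gene CLDN1 stood at 2.00 ± 0.899 CPM against 0.435 ± 0.424 CPM in WT. ESRP2 stood at 1.77 ± 1.19 against 0.338 ± 0.331 CPM and EPCAM at 2.98 ± 1.15 against 1.16 ± 0.551 CPM. ATF4 targets and integrated stress response, the genes cells induce when eIF2alpha is phosphorylated, were not called as a list. Of its 39 members 9 were higher and 4 lower, 10 higher and 5 lower adjusted over the list alone, with a median of 0.17 (adjusted p = 0.198). The amino acid transporter SLC7A5 changed by -1.07 ± 0.16, and ASNS, asparagine synthetase, by 0.99 ± 0.17. Cytosolic ribosomal proteins had a median of 0.01 and a mean of -0.04, with 7 of 81 lower both over all genes and adjusted over the list alone (adjusted p = 0.403). With no filter on low counts the epithelial list lost its call (adjusted p = 0.0900). The count of 1315 genes rose to 2022 without CTU2 2 h replicate 1, and came to 43 with 0 h libraries only (38 higher) and 353 with labelled libraries only (205 higher).

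The comparison of the CTU2 knockout with WT asks how cells labelled as lacking the thiolation step, which was not measured, differ. Its clearest change was a rise of ATF4 targets and integrated stress response. NUPR1, a stress-induced transcriptional regulator, went from 0.338 ± 0.335 CPM in WT to 19.4 ± 8.04 CPM (5.68 ± 0.44; adjusted p = 5.82e-09). ASNS went from 247 ± 88.4 to 1150 ± 508 CPM (2.19 ± 0.17; adjusted p = 7.27e-09). ASNS shares reads with ENSG00000284707, so its own level is uncertain. PSAT1, of serine synthesis, rose by 1.31 ± 0.12, the glycine transporter SLC6A9 by 2.42 ± 0.23 and CHAC1, which degrades glutathione, by 2.28 ± 0.25. Of the 39 members 20 were higher and none lower, and 25 were higher adjusted over the list alone. A positive change was seen in 37. The list median was 0.75 with quartiles of 0.32 and 1.28 (camera adjusted p = 5.73e-38; adjusted p = 4.52e-05 with an estimated correlation).

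Outside that list, BEX1 (ENSG00000133169, chromosome X, 103062651 to 103064171) fell from 35.2 ± 2.98 CPM in WT to 0.146 ± 0.176 CPM in the CTU2 knockout (-7.68 ± 0.30; adjusted p = 7.26e-15). NRXN3, a presynaptic adhesion protein, changed by -5.51 ± 0.35 (adjusted p = 1.36e-10). TWIST2, a mesenchymal transcription factor, had 298 reads over the WT libraries and 2 over the CTU2 knockout libraries, a ratio of 165 with a 95% counting interval of 45.2 to 1370. The other largest falls were in UNCX (-4.16), SNAI2 (-2.52), FOXF1 (-2.46), LYPD1 (-2.01), CNN2 (-1.71) and the small RNA SCARNA8 (-1.62), beside CTU2 itself, with adjusted p from 3.40e-09 to 8.30e-05. The other largest rises were in the U5 small nuclear RNA genes RNU5F-1 (3.16) and RNU5B-1 (2.59), NIBAN1 (2.93), ANK1 (2.33), the Hedgehog receptor gene PTCH2 (2.04) and STXBP6 (2.03), with adjusted p from 1.64e-11 to 5.21e-05. In all, 519 genes were higher and 378 lower, and 291 of them changed by at least 1 on the log2 scale, 165 higher and 126 lower. The balance turned with 0 h and 1 h libraries only, to 266 higher and 348 lower. The median absolute change of called genes was 0.76.

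Cytosolic ribosomal proteins rose in the CTU2 knockout by a median of 0.43, with 32 of 81 higher and 1 lower, and 59 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.47e-21; adjusted p = 0.131 with an estimated correlation). RPL4 changed by 0.81 ± 0.16, RPL22L1 by 0.77 ± 0.14, RPLP1 by 0.63 ± 0.12 and RPLP0 by 0.57 ± 0.12. Nuclear-encoded oxidative phosphorylation had 10 of 53 higher, 24 adjusted over the list alone, and a median of 0.36 (adjusted p = 4.61e-09; adjusted p = 0.217 with an estimated correlation). COX7B changed by 0.70 ± 0.14 and NDUFA1 by 0.66 ± 0.14. Cytosolic aminoacyl-tRNA synthetases had 5 of 22 higher and 1 lower, 6 and 1 adjusted over the list alone, and a median of 0.20 (adjusted p = 0.0120; adjusted p = 0.217 with an estimated correlation). MARS1 changed by 0.85 ± 0.13 and YARS1 by 0.83 ± 0.14. Neuronal markers had 4 of 14 higher, 7 adjusted over the list alone, and a median of 0.38 (adjusted p = 0.0167; adjusted p = 0.0751 with an estimated correlation). The neurofilament gene INA changed by 0.65 ± 0.12. Epithelial markers had 3 of 8 higher, also 3 adjusted over the list alone, and a median of 0.44 (adjusted p = 0.0208; adjusted p = 0.0751 with an estimated correlation). Lower lists were heat shock and cytosolic chaperones, with 3 of 24 lower, 5 adjusted over the list alone, and a median of -0.19 (adjusted p = 0.00014; adjusted p = 0.0534 with an estimated correlation). Splicing factors of the SR family had 5 of 18 lower, 6 adjusted over the list alone, and a median of -0.26 (adjusted p = 0.00088; adjusted p = 0.208 with an estimated correlation). TRA2A changed by -0.66 ± 0.15. Cholesterol biosynthesis had 4 of 23 lower, 6 lower and 2 higher adjusted over the list alone, and a median of -0.19 (adjusted p = 0.0057; adjusted p = 0.0698 with an estimated correlation). MSMO1 changed by -0.92 ± 0.17 and INSIG1 by -0.68 ± 0.13. Replication and S phase had 2 of 24 lower, also 2 adjusted over the list alone, and a median of -0.17 (adjusted p = 0.0167; adjusted p = 0.0751 with an estimated correlation). CCNE1, cyclin E1, changed by -0.99 ± 0.17 and CDC6 by -0.61 ± 0.12. Of these lists the epithelial one lost its call with no filter on low counts (adjusted p = 0.261), and the aminoacyl-tRNA synthetases and neuronal markers with labelled libraries only (adjusted p of 0.0536 and 0.0538). The 897 calls fell to 554 without CTU2 0 h replicate 1, 558 without WT 0 h replicate 1 and 575 without WT 2 h replicate 1. They came to 25 for 0 h libraries only and 203 for labelled libraries only. Without the 2 libraries called as standing apart, CTU2 2 h replicate 1 and ELP1 0 h replicate 2, they came to 1396.

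**Figure D2:**
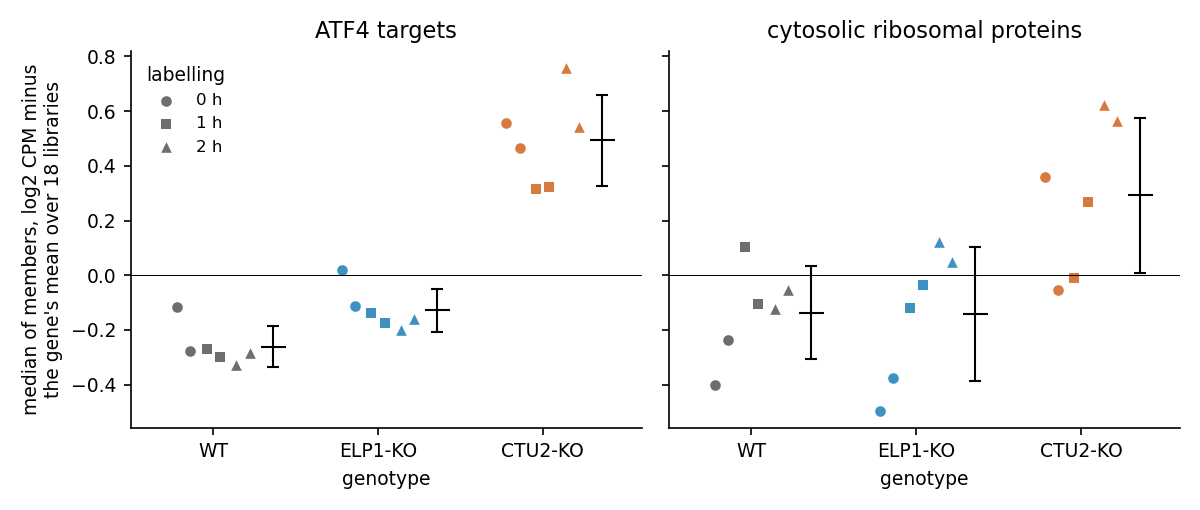
Median level per library, in log2 CPM relative to the mean of all libraries, of ATF4 targets and integrated stress response and of cytosolic ribosomal proteins, by genotype and labelling time. The ATF4 list averaged 0.49 in the CTU2 knockout and -0.26 in WT, and the ribosomal list 0.29 and -0.14.

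The direct comparison of the knockouts asks where the cells labelled as lacking the mcm5 step and those labelled as lacking the thiolation step differ. ATF4 targets and integrated stress response were lower in the ELP1 knockout than in the CTU2 knockout in 21 of 39 members, and 31 adjusted over the list alone, with a median of -0.61 (camera adjusted p = 5.94e-27; adjusted p = 0.000335 with an estimated correlation). NUPR1 differed by -4.19 ± 0.37, SLC7A5 by -1.34 ± 0.16, SESN2 by -1.14 ± 0.14 and PSAT1 by -0.95 ± 0.12. All 81 cytosolic ribosomal proteins had a negative difference, of which 32 were called and 65 adjusted over the list alone, with a median of -0.40 (adjusted p = 1.11e-24; adjusted p = 0.235 with an estimated correlation). RPL22L1 differed by -1.28 ± 0.14 and RPL29 by -1.05 ± 0.12. Nuclear-encoded oxidative phosphorylation had 5 of 53 lower, 7 adjusted over the list alone, and a median of -0.19 (adjusted p = 0.000148; adjusted p = 0.589 with an estimated correlation). Cholesterol biosynthesis had 3 of 23 lower, 4 adjusted over the list alone, and a median of -0.17 (adjusted p = 0.0334; adjusted p = 0.235 with an estimated correlation). EBP differed by -0.64 ± 0.14. BEX1 (7.605 ± 0.30), PCSK2 (6.16 ± 0.39) and BMP2 (6.11 ± 0.34) were higher in the ELP1 knockout. SOX11 had no read in the CTU2 knockout libraries and was at least 179-fold higher in the ELP1 knockout, taking 3 reads over the group as the limit. PTN had 325 reads against 2, a ratio of 163 with a 95% counting interval of 44.8 to 1350. STXBP6 (-2.33), MAP7D2 (-2.08), RNU5F-1 (-1.71) and FIRRE (-1.67) were lower. In all 471 genes were higher and 542 lower, with a median absolute change of 0.72 and 294 past 1 on the log2 scale, 207 higher and 87 lower. The cholesterol list lost its call in 4 of the fits without 1 library, without CTU2 0 h replicate 2 (adjusted p = 0.0544), CTU2 2 h replicate 2 (0.0601), ELP1 0 h replicate 1 (0.0585) or ELP1 1 h replicate 1 (0.0596). It also lost it with labelled libraries only (0.125), with 0 h and 1 h libraries only (0.0919) and with the length trend removed (0.0725). The 1013 calls fell to 619 without CTU2 0 h replicate 1. They came to 17 for 0 h libraries only (16 higher), 219 for labelled libraries only (130 higher) and 672 for 0 h and 1 h libraries only (398 higher), so the balance towards lower genes turned in each.

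Genes called in both knockouts moved mostly together. UNCX, FOXF1 and its divergent noncoding neighbour FENDRR (-3.97 ± 0.41 in the ELP1 and -2.05 ± 0.33 in the CTU2 knockout) were lower in both. HSPA1A, an inducible HSP70 gene, fell by 3.99 ± 0.48 in the ELP1 knockout. It had 2 reads over the CTU2 knockout libraries against 171 in WT, a ratio of 94.6 with a 95% counting interval of 25.8 to 787. Its near-identical copy HSPA1B makes the assignment of its reads uncertain. The phosphatase gene DUSP2 changed by -1.88 ± 0.40 in the ELP1 knockout and had 2 reads in the CTU2 knockout against 84 in WT, a ratio of 46.4 (12.5 to 390). Higher in both were FAAH2 (3.26 ± 0.54 and 3.24 ± 0.54), the protocadherin gene PCDHB16 (3.11 ± 0.61 and 2.75 ± 0.63), LRRC7, ZNF85 and TMEM202. LRRC7 had 3 reads in WT against 82 and 50, ratios of 24.8 (8.2 to 123) and 15.1 (4.87 to 75.5). ZNF85 had 3 reads against 44 and 38, ratios of 13.3 (4.27 to 67) and 11.5 (3.63 to 58). TMEM202 had none in WT and was at least 13.9-fold higher in the ELP1 and at least 20.8-fold higher in the CTU2 knockout. In all 206 genes were higher and 126 lower in both, and 18 were called in opposite directions, where independent lists of these sizes would share 25.9 and 17.9. Because both comparisons use the same WT libraries, unchanged groups were simulated against them, which gave a mean of 0.05 shared calls over 20 draws. These draws held no changed gene and gave a mean of 0.1 calls per knockout, so few shared calls were possible. Their count cannot tell how many of the observed shared calls come from the shared WT libraries. The covariance of the fold changes across genes was 0.111, against 0.0342 in the simulated groups, a difference of 0.0766. The correlation of the fold changes was 0.464 and 66.1% had the same sign, no more than the 0.507 and 66.7% of the simulated groups. Shared WT libraries alone thus give values as high, so with them these measures neither show nor exclude agreement. With the WT libraries divided between the knockouts by replicate number, 56 and 60 genes were shared. Independent lists would share 2.83 and 1.91 or 1.53 and 1.32. In these fits, where the knockouts share no WT library, the correlation was 0.323 and 0.319. The same sign was seen in 57.8 and 62.8% of genes, so some agreement was left without shared WT libraries. The 332 shared calls came to 182 without WT 0 h replicate 1, 220 without WT 2 h replicate 1, and 513 without CTU2 2 h replicate 1. They came to 7 with 0 h libraries only, 74 with labelled libraries only and 574 without the 2 libraries that stand apart.

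**Figure D3:**
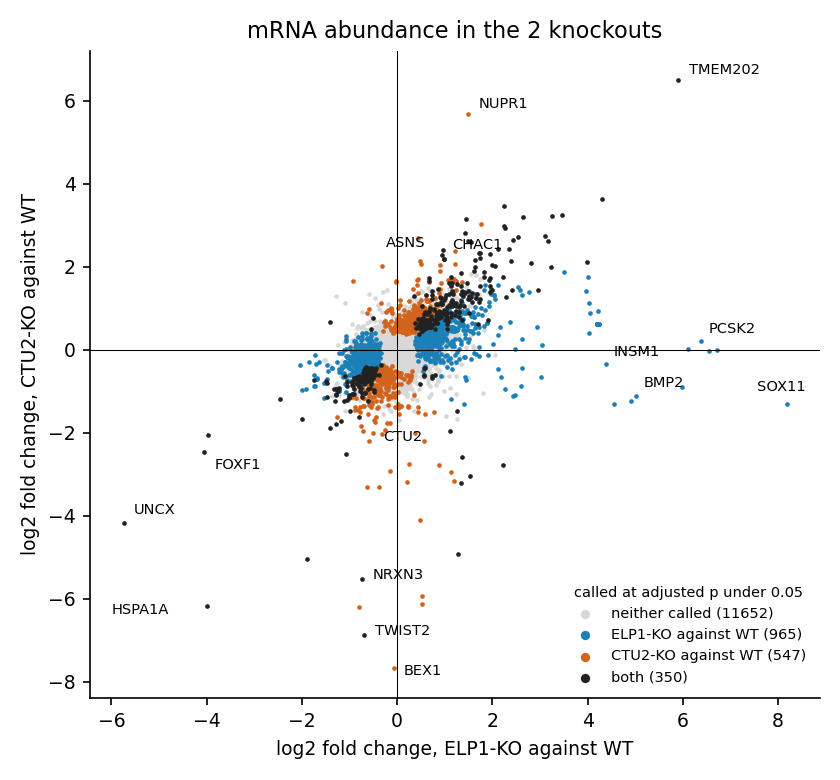
Fitted log2 fold change of each of the 13514 tested genes in the ELP1 knockout (horizontal) and the CTU2 knockout (vertical) against WT, coloured by the comparison in which it was called. Most of the 350 genes called in both lie in the lower left or upper right, 332 of them, and fitted values of genes with few reads are not bounds.

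Labelling with s4U was measured directly by the conversion rate. In exonic reads 0.0395 to 0.0496% of T positions read as C in unlabelled libraries, 0.256 to 0.432% after 1 h and 0.585 to 0.933% after 2 h. The mean over labelled libraries was 0.504 ± 0.295% in WT, 0.619 ± 0.302% in the ELP1 knockout (exact two-sided permutation p = 0.543, n = 4) and 0.540 ± 0.168% in the CTU2 knockout (exact p = 0.800, n = 4). These means hold both labelling times, whose rates differ more than the genotypes do. Exchanging libraries only within a labelling time, a test added after the data were seen, gave exact permutation p = 0.111 and 0.611, where 36 arrangements allow 0.0556 at the least. At 1 h the rate was 0.345 and 0.376% in the ELP1 knockout and 0.386 and 0.432% in the CTU2 knockout, above the 0.256 and 0.259% of WT. At 2 h it was 0.823 and 0.933%, 0.757 and 0.585%, and 0.846 and 0.654%. In introns each ELP1 knockout library was above both WT libraries of its time, by means of 0.647 percentage points at 1 h and 0.446 at 2 h (exact permutation p = 0.0556). The CTU2 knockout differed there by 0.653 at 1 h and -0.482 at 2 h (exact permutation p = 0.667). The new-to-total ratio of each transcript gave a turnover rate, and its median over genes in WT after 2 h matched a half-life of 6.22 h, with quartiles of 3.03 and 11.03 h. Immediate early genes, which cells switch on and clear fast, turned over at the limit of the measure after 2 h, when JUN, ID3 and IER5 were entirely new. The list median of 0.301 h is the shortest value that the limited ratio allows and sets no bound, and the 1 h libraries gave 0.489 h. After 1 h in WT the new share was 93.0 ± 9.85% for JUN, 58.3 ± 0.771% for IER5 and 45.9 ± 4.85% for ID3 (n = 2). Zinc finger ZNF genes had a median half-life of 1.52 h, p53 targets 2.83 h, hypoxia response 3.49 h and m6A writers, readers and erasers 3.81 h. Only members with enough reads count here, 76, 9, 9 and 22 for these lists and 13 for immediate early genes. At the other end stood glycolysis with 16.2 h, nuclear-encoded oxidative phosphorylation with 16.9 h and cytosolic ribosomal proteins with 20.1 h. RPL27A was 3.70 ± 1.37% new after 2 h in WT, RPS29 4.31 ± 1.53% and RPS4X 5.90 ± 2.45%. Of glycolysis, ENO1 was 8.50 ± 3.32% new, LDHB 8.94 ± 1.81% and LDHA 8.995 ± 3.66%. The 1 h libraries gave longer values, with a median of 9.69 h over all genes. The hypoxia list stood at 9.87 h there, so its place among the short-lived lists held at 2 h only. Zinc finger ZNF genes stood at 3.88 h and p53 targets at 3.395 h, so their order turned.

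**Figure D4:**
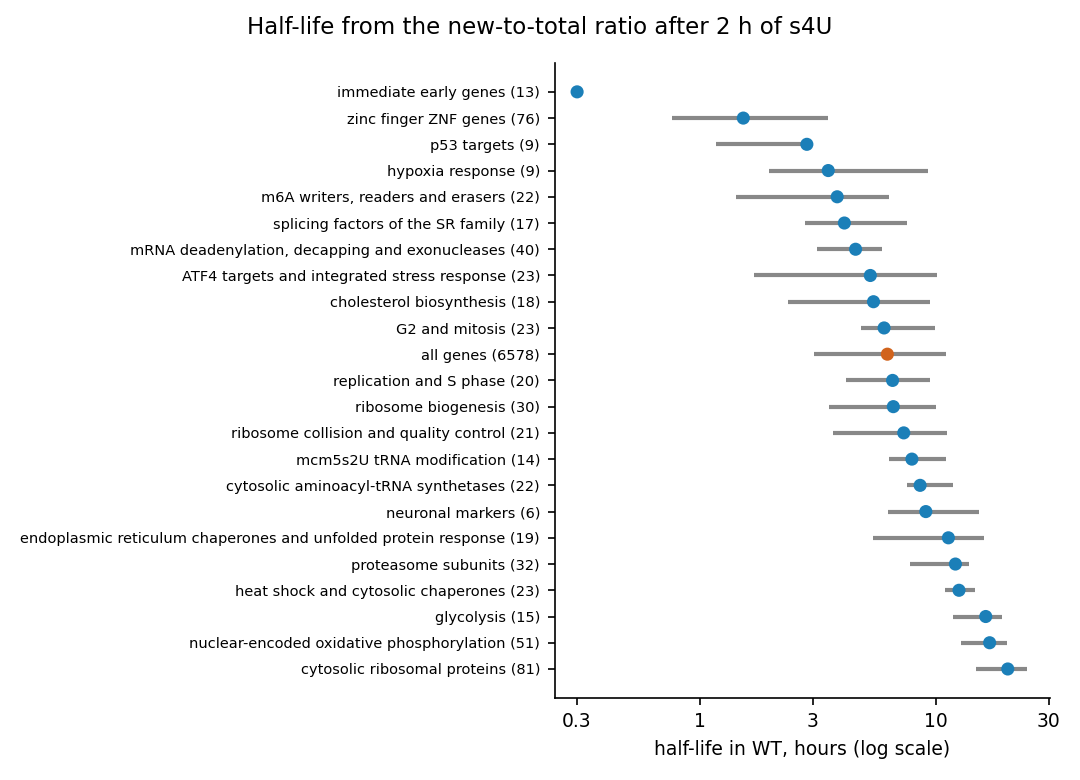
Half-life in hours, on a log axis, of the genes of each list in WT after 2 h of labelling, with the dot at the median and the bar from the lower to the upper quartile. Medians ran from 0.301 h for immediate early genes, the shortest value the limited ratio allows, to 20.1 h for cytosolic ribosomal proteins, with 6.22 h for all genes.

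The series title concerns m6A and decay. The turnover comparison asks only whether the turnover of single genes and lists differed between genotypes. It did not separate genes by m6A sites or codon content. No gene passed the threshold for a changed turnover rate in either knockout. The median log2 turnover rate per hour was -3.46 ± 0.27 in the ELP1 knockout and -3.43 ± 0.39 in WT (difference -0.03, exact two-sided permutation p = 0.943, n = 4). It was -3.38 ± 0.28 in the CTU2 knockout (difference 0.05, exact p = 0.8286), where the smallest p that the 70 arrangements allow is 0.0286. These means also hold both labelling times. The CTU2 difference was 0.501 with 1 h libraries only and -0.397 with 2 h libraries only, and the ELP1 difference 0.0597 and -0.116, so a mean near 0 does not show that the genotypes agreed at each time. Within labelling times the exact permutation p was 0.889 for the ELP1 and 0.833 for the CTU2 knockout. Relative to the median gene of each library, limma called 0 of 6578 genes in the ELP1 knockout, 0 in the CTU2 knockout and 0 between them, while 514, 502 and 419 had an unadjusted p under 0.05. With inverse posterior variance weights limma called 62, 36 and 19. The genes with the smallest adjusted p, chosen after their values were seen, were CBX6 in the ELP1 knockout (0.96 ± 0.14, adjusted p = 0.0528) and HSPA1B in the CTU2 knockout (1.09 ± 0.17, adjusted p = 0.153). Cytosolic ribosomal proteins had a median change in turnover of -0.20 in the ELP1 knockout (adjusted p = 0.0240; adjusted p = 0.488 with an estimated correlation) and -0.18 in the CTU2 knockout (adjusted p = 0.000811; adjusted p = 0.478 with an estimated correlation), with 0 of 81 called in each, and 2 and 1 lower adjusted over the list alone. Nuclear-encoded oxidative phosphorylation had medians of -0.22 (adjusted p = 0.0463; adjusted p = 0.488 with an estimated correlation) and -0.31 (adjusted p = 0.00306; adjusted p = 0.478 with an estimated correlation), with 0 of 51 called, and 1 and 3 adjusted over the list alone. Without WT 2 h replicate 1 the adjusted p was 0.388 for both lists in the ELP1 and 0.110 for both in the CTU2 knockout. In the ELP1 knockout the ribosomal list also lost its call in 3 and the oxidative phosphorylation list in 6 of the other fits without 1 library. Other alternatives ended both ELP1 calls, namely 1 h libraries only (adjusted p = 0.755 for both), no centring (0.0694 for both), the logit of the ratio (0.0871 for both), at least 30 reads (0.0790 and 0.118) and only the 2 genotypes compared (0.0578 and 0.0718). The posterior mean ended the ribosomal call (0.107) and a replicate block that of oxidative phosphorylation (0.0559). Both CTU2 calls ended with 2 h libraries only (0.138 and 0.534). Some ribosomal ratios lay near the lower limit of 0.01 at 1 h, where RPL27A was 1.115 ± 0.106% new in WT and RPS4X 2.395 ± 0.149%. Over all genes, 280 (CTU2 1 h replicate 2) to 623 (WT 1 h replicate 2) ratios per 1 h library lay below that limit. The limit thus did not act equally on the libraries. On simulated data of this design limma recovered 7.46% of genes with turnover changed by 1 and 63.6% of those changed by 2 on the log2 scale, so smaller changes in decay were not detectable.

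New RNA was set beside abundance, which its formula contains as a factor, so an agreement of their signs is expected and tests nothing. Among genes higher in the ELP1 knockout, 200 of the 240 with a ratio had more new RNA (median 0.40), and among lower genes 349 of 414 had less (median -0.46). In the CTU2 knockout these were 237 of 274 (median 0.39) and 166 of 187 (median -0.43). Turnover went the opposite way to abundance in 159 of the 240, 234 of the 414, 197 of the 274 and 118 of the 187, with medians of -0.17, 0.09, -0.21 and 0.14. Turnover uses the same libraries as abundance, so its signs are not independent of it either. INSM1, named after its value was seen, was the single gene limma called in new RNA in the ELP1 knockout (4.42, adjusted p = 3.82e-05), with 362 at an unadjusted p under 0.05. In the CTU2 knockout limma called 0, with 311 at an unadjusted p under 0.05 and the smallest adjusted p of 0.0789 in ASNS. Its difference from WT over all genes had a median of 0.378 with 1 h libraries only (749 at an unadjusted p under 0.05) and -0.377 with 2 h libraries only (1592), so the value over both times averages opposite ones. New RNA of ATF4 targets and integrated stress response was higher in the CTU2 knockout in 22 of 23 members, with a median of 0.63 and 4 adjusted over the list alone (camera adjusted p = 1.30e-10; adjusted p = 0.118 with an estimated correlation). New RNA of cholesterol biosynthesis was lower by a median of -0.46 in the ELP1 knockout, with 0 of 18 called, also 0 adjusted over the list alone (adjusted p = 0.00568; adjusted p = 0.449 with an estimated correlation). In the CTU2 knockout its median was -0.28, with 2 lower adjusted over the list alone (adjusted p = 0.0139; adjusted p = 0.438 with an estimated correlation). That of cytosolic ribosomal proteins was 0.27, with 0 adjusted over the list alone (adjusted p = 0.000129; adjusted p = 0.976 with an estimated correlation). The cholesterol call ended in the ELP1 knockout without ELP1 2 h replicate 1 (adjusted p = 0.0674) and in the CTU2 knockout without CTU2 1 h replicate 1 (0.104) or 2 (0.0951). The ribosomal call ended without CTU2 2 h replicate 1 (0.112) or WT 2 h replicate 2 (0.0881). The cholesterol calls also ended with at least 300 reads (0.0528 in the ELP1 and 0.160 in the CTU2 knockout), with 1 h libraries only in the ELP1 knockout (0.185) and with 2 h libraries only in the CTU2 knockout (0.623). The ribosomal call also ended with 1 h libraries only (0.812).

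Total read counts of some genes differed between 2 h of s4U and 0 h. Whether RNA levels changed with the counts was not tested. CENPE, a mitotic kinesin, fell from 110 to 20.8 CPM in WT (-2.40 ± 0.31), from 137 to 13.9 CPM in the ELP1 knockout (-3.30 ± 0.32) and from 85.3 to 9.83 CPM in the CTU2 knockout (-3.11 ± 0.33; n = 2 per group). TRIP11, a Golgi protein with a long transcript, changed by -2.26 ± 0.36, -3.09 ± 0.38 and -3.65 ± 0.43. AKAP9 (-2.24), SNORA79B (-2.05) and CEP290 (-1.995) were also lower in WT. In the ELP1 knockout TEX15 (-3.81), SNORA44 (-2.84) and SNORA6 (-2.82) were lower, and in the CTU2 knockout TEX15 (-3.53), BRCA2 (-3.07) and GOLGA4 (-2.999). Higher were ENSA (1.40), RPL17 (1.57) and its read-through transcript RPL17-C18orf32 (1.40) in the ELP1 knockout, and PLPPR2 (1.63), HSD17B8 (1.58), HIRA (1.53) and SLC39A4 (1.52) in the CTU2 knockout. The pseudogenes MTCO1P12 (2.95 in the ELP1 and 2.75 in the CTU2 knockout) and MTND4P12 (2.96 in the ELP1 knockout) are near-identical copies of mitochondrial genes, and RPL17 overlaps its read-through, so the assignment of their reads is uncertain. Against 0 h, edgeR called 9 genes in WT (1 higher, 8 lower) and 108 in the ELP1 knockout (20 higher, 88 lower). It called 754 in the CTU2 knockout (214 higher, 540 lower). In WT DESeq2, run without the filter on low counts, called 27 higher and 17 lower. The balance in WT thus turned where tool and filter changed together. For a change from 0 to 2 h that differed from WT, edgeR made 0 calls in the ELP1 knockout (441 at an unadjusted p under 0.05, and 0 by DESeq2) and 0 in the CTU2 knockout (958, and 14 by DESeq2). For the CTU2 knockout this count came to 44 with no filter on low counts and to 940, of which 913 were lower, without CTU2 2 h replicate 2, so whether its response differed from WT stays open. After 1 h edgeR and DESeq2 called 0 genes in each genotype, with 471, 685 and 413 at an unadjusted p under 0.05 in WT, the ELP1 and the CTU2 knockout. Cytosolic ribosomal proteins were higher after 2 h by medians of 0.23, 0.56 and 0.44 in WT, the ELP1 and the CTU2 knockout, with 0, 5 and 6 of 81 higher and 0, 40 and 14 adjusted over the list alone (adjusted p of 1.96e-06, 3.78e-26 and 1.79e-10; adjusted p = 0.560, 0.206 and 0.371 with an estimated correlation). Proteasome subunits were higher by 0.17, 0.32 and 0.43, with 0, 0 and 4 of 32 higher and 3, 0 and 9 adjusted over the list alone (adjusted p of 0.000103, 3.49e-06 and 0.000763; adjusted p = 0.441, 0.206 and 0.341 with an estimated correlation). Zinc finger ZNF genes were lower by -0.20 in the ELP1 and -0.32 in the CTU2 knockout, with 4 and 34 of 393 lower and 4 and 36 adjusted over the list alone (adjusted p of 0.00910 and 0.000377; adjusted p = 0.392 and 0.341 with an estimated correlation).

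The labelling calls depended on single libraries, since each group held 2. The 9 calls in WT came to 0 without WT 2 h replicate 1, 1 without WT 0 h replicate 1, 3 without WT 0 h replicate 2, and 15 without either CTU2 2 h or either ELP1 0 h library. The 108 in the ELP1 knockout came to 11 without ELP1 2 h replicate 2, 20 without ELP1 2 h replicate 1, 49 without ELP1 0 h replicate 2, 179 without ELP1 0 h replicate 1 and 175 without CTU2 2 h replicate 1 or 2. The 754 in the CTU2 knockout came to 60 without CTU2 0 h replicate 2, 95 without CTU2 2 h replicate 1, 2963 without CTU2 2 h replicate 2, 474 and 471 without CTU2 1 h replicate 1 and 2, and 498 without WT 1 h replicate 1 or 2. CENPE, TRIP11 and TEX15 stayed lower and called in the ELP1 knockout in every fit without 1 library, as did these and BRCA2 and GOLGA4 in the CTU2 knockout. The other genes named for labelling each lost their call in at least 1 such fit. Changes at 2 h also followed transcript length, with a Spearman correlation of log2 fold change and length of -0.125 in WT, -0.275 in the ELP1 and -0.323 in the CTU2 knockout. With that trend removed the medians of cytosolic ribosomal proteins fell to 0.16, 0.36 and 0.34 and stayed called (adjusted p of 0.00295, 1.65e-13 and 0.000124). The zinc finger list lost its call in the ELP1 knockout without ELP1 0 h replicate 2 (adjusted p = 0.113), and with the length trend removed (0.0530).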

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

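The tests of a single library, of the balance of higher and lower genes, of a labelling response common to the genotypes, of shared reads and of synthesis were chosen after the results were seen, and the fits with 0 h and 1 h libraries only or with the length trend removed were added after the data were seen but before the values they gave.

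A rise of ATF4 targets and integrated stress response in the CTU2 knockout (list median 0.75) set it apart from the ELP1 knockout, with a tested difference of -0.61 between them. The libraries that stand apart did not make it, since without these 2 libraries the median was 0.67. With 0 h and 1 h libraries only, which keeps ELP1 0 h replicate 2, the median was 0.72. The library difference was then 0.655 ± 0.0716 (SE, exact permutation p = 0.0286, the smallest possible). Removing the length trend gave 0.80, and leaving out the 1 member that shares reads gave 0.73 over the other 38. Higher synthesis may account for part of the rise, since intronic reads of the list were higher by a median of 0.52 in 20 of 24 members (camera adjusted p = 0.000347 with an estimated correlation). An effect of the loss of CTU2 and a difference between clones both stay open and were not tested, since the labels name no clones.

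Cytosolic ribosomal protein mRNAs were higher in the CTU2 knockout (list median 0.43), and lower by -0.40 in the ELP1 than in the CTU2 knockout (camera adjusted p = 1.11e-24; adjusted p = 0.235 with an estimated correlation). Without the 2 libraries that stand apart the median was 0.41, so these libraries made little of it. With 0 h and 1 h libraries only, which leaves out both CTU2 2 h libraries but keeps ELP1 0 h replicate 2, the median was 0.31. The library difference was then 0.301 ± 0.147 (SE), with an exact permutation p of 0.114 against 0.0130 over all times. Removing the length trend left 0.33, so a trend on length was not the whole cause either. These genes move together from library to library, which is why the call against WT was lost with an estimated correlation (adjusted p = 0.131). A difference between genotypes or clones stays open and was not tested apart.

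After 2 h of s4U in the CTU2 knockout 540 genes were lower, by a median of -1.49, and 214 higher. How far CTU2 2 h replicate 1 made this stays open, since without it 95 genes were called, 83 of them lower, and without replicate 2 it was 2963, while a group left with 1 library also has less power. The lower genes had a median length of 6759 bases against 3636.5 for all tested genes. With the length trend removed 515 calls were left, 352 of them the same genes, so length was not the whole cause of the calls. The excess of lower genes was not kept, since 282 were then higher and 233 lower, 45.2% of calls against 71.6% before. The lower genes were long and entered the fit of that trend, so its removal takes out part of their fall whatever the cause. A trend on length may account for that excess, and whether the trend is technical or a loss of long transcripts under s4U was not tested. A response to s4U common to the genotypes may account for part, since the same genes had a median of -0.33 in WT, 86.1% of them below 0, and -0.54 in the ELP1 knockout. The size in the CTU2 knockout stays open, as the difference from WT was called for 0 genes by edgeR (958 at an unadjusted p under 0.05, DESeq2 14), for 44 with no filter on low counts and for 940 without CTU2 2 h replicate 2. At 1 h the median of the lower genes in the CTU2 knockout was 0.24.

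Genes differing between the knockouts numbered 1013, as tested directly. Nuclear-encoded oxidative phosphorylation was lower in the ELP1 than in the CTU2 knockout by a median of -0.19 (camera adjusted p = 0.000148; adjusted p = 0.589 with an estimated correlation) and cholesterol biosynthesis by -0.17 (adjusted p = 0.0334; adjusted p = 0.235). The cholesterol call was also lost in 4 fits without 1 library, without CTU2 0 h replicate 2 (0.0544), CTU2 2 h replicate 2 (0.0601), ELP1 0 h replicate 1 (0.0585) or ELP1 1 h replicate 1 (0.0596). It was lost too with labelled libraries only (0.125), 0 h and 1 h libraries only (0.0919) and the length trend removed (0.0725).

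Intronic reads, outside the main measurement, called 213 genes in the ELP1 knockout and 124 in the CTU2 knockout against WT with edgeR. In labelled libraries at least 1.97% of covered T positions in introns were converted, against at most 0.0958% in unlabelled ones.

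In all, 156 groups of values were tested, of named genes and library measures (6 libraries of a genotype) and of median turnover (4 labelled libraries). Of these 14, all of named genes, held a library far from the others, where chance gives 7.8 for normal values. SOX11, PTN and HSPA1A were flagged only because every other library of the genotype held 0. An excess over chance is thus not shown. In WT, SOX11 stood at 0.199 CPM in 2 h replicate 2 and 0 elsewhere, and STXBP6 at 3.27 CPM in 2 h replicate 1 against 2.19 to 2.58. In the ELP1 knockout at 0 h, replicate 1 held 7.97 CPM of NOTCH1 (1.25 to 2.70 elsewhere), 10.4 of PTCH2 (2.68 to 4.67) and 26.8 of SNAI2 (6.66 to 11.9), and replicate 2 held 14.4 CPM of FIRRE (5.09 to 7.60) and 12.1 of CTU2 (18.05 to 19.8). In the same genotype STXBP6 stood at 4.89 CPM in 1 h replicate 2 against 0.886 to 2.32. In the CTU2 knockout 2 h replicate 1 held 65.1 CPM of CCND1 (37.8 to 46.2 elsewhere), 33.5 of SLC6A9 (16.6 to 21.5) and 17.3 of CNN2 (5.86 to 8.87). Also in the CTU2 knockout, 1 h replicate 1 held 0.501 CPM of PTN (0 elsewhere) and 3.76 of ZNF85 (0.532 to 1.63), and 0 h replicate 1 held 0.355 CPM of HSPA1A (0 elsewhere).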

How the results depend on the processing

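Fits without the 2 libraries that stand apart, with 0 h and 1 h libraries only and with the length trend removed, and the alternatives of the overlap other than the division of WT and of the conversion rates, and the permutations within labelling times, were chosen after the data were seen. Over 22 main results and 463 alternatives, 375 values stayed on their side or within 1.5 times, 75 moved further and 13 changed sign. Over 274 named values and 7810 alternatives 6720 kept direction and call, 1083 lost the call, 3 gained it and 4 changed sign. Over 61 called lists and 1512 alternatives 1355 kept the call, 156 lost it and 1 changed sign. The codon comparisons were not run, for want of coding sequences. Causes were not tested except where fewer libraries or genes were used.

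DESeq2 called 44 genes in WT and 195 in the ELP1 knockout at 2 h of labelling and 14 for the CTU2 labelling response. With no filter on low counts these were 62, 240 and 44, with 1214 in the CTU2 knockout at 2 h and 5 in the ELP1 knockout at 1 h. Abundance calls for ELP1 against WT, CTU2 against WT and ELP1 against CTU2 were 43, 25 and 17 with 0 h libraries only, 353, 203 and 219 with labelled libraries only, and 379, 291 and 294 with an absolute log2 fold change of at least 1. With only the 2 genotypes compared ELP1 against WT had 2043 and ELP1 against CTU2 584. Without the 2 libraries that stand apart CTU2 against WT had 1396, and 2 h labelling 35 in WT and 168 in the CTU2 knockout. With 0 h and 1 h libraries only ELP1 against CTU2 had 672. With a replicate block the abundance calls were 1307, 892 and 984. Shared calls of the knockouts were 7 with 0 h libraries only, 74 with labelled libraries only, 108 with an absolute change of at least 1, 574 without the 2 libraries that stand apart, 220 with 0 h and 1 h libraries only, and 56 and 60 with WT divided by replicate number.

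Leaving out each library in turn gave 878 to 2022 calls for ELP1 against WT, 554 to 1145 for CTU2 against WT and 619 to 1075 for ELP1 against CTU2. It gave 0 to 15 for 2 h labelling in WT, 11 to 179 in the ELP1 and 60 to 2963 in the CTU2 knockout. It gave 0 to 940 for the CTU2 labelling response (940 without CTU2 2 h replicate 2), 0 to 1 for turnover of ELP1 against CTU2 (1 without WT 1 h replicate 1), and 182 to 513 shared calls. The difference in median log2 turnover rate ran from -0.152 to 0.143 for the ELP1 and -0.0716 to 0.223 for the CTU2 knockout, and that of the conversion rate in percent from 0.0107 to 0.229 for the ELP1 (without ELP1 2 h replicate 2 and WT 2 h replicate 1) and -0.0464 to 0.150 for the CTU2 knockout.

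Turnover calls for ELP1 against WT were 1 with the posterior mean of the ratio, 1 with a mean read count of at least 300, 1 with the logit of the ratio and 1 with 1 h libraries only. For CTU2 against WT they were 1 with the posterior mean and 1 with at least 300 reads, and for ELP1 against CTU2 1 with 1 h libraries only. Inverse posterior variance weights gave 62, 36 and 19. New RNA calls were 0 for ELP1 and 2 for CTU2 with at least 300 reads, and for ELP1 2 with 1 h libraries only and 0 with 2 h libraries only. Of the 61 list calls over all comparisons 5 held with an estimated correlation. Differences in median turnover changed sign to 0.0597 for ELP1 with 1 h libraries only, and for CTU2 to -0.0285 with the posterior mean and -0.397 with 2 h libraries only, and the CTU2 conversion difference to -0.0792 with 2 h libraries only. ELP1 mRNA in the CTU2 knockout changed from -0.08 to 0.0182 with 0 h libraries only, 0.0157 without the 2 libraries that stand apart, 0.0189 with 0 h and 1 h libraries only and 0.0200 without CTU2 2 h replicate 1. Leaving out each library gave it -0.136 to 0.0200, and the immediate early list at 2 h in the ELP1 knockout -0.531 to 0.209 (0.209 without ELP1 0 h replicate 1). At 3482642 to 6400584 exonic reads, changes of 0.5 on the log2 scale were mostly missed (7.46% recovered on simulated counts for the CTU2 knockout against WT).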

Other observations

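The counts of calls under other divisions of the libraries and the tests on intronic reads were chosen after the results were seen.

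Some stress and signalling genes changed in the same direction in both knockouts. JUN, an AP-1 transcription factor, rose by 0.98 ± 0.12 in the ELP1 and 0.95 ± 0.12 in the CTU2 knockout (edgeR adjusted p = 5.02e-06 and 9.09e-06), while immediate early genes as a list had 5 higher and 4 lower of 33 in the ELP1 and 5 higher and 3 lower in the CTU2 knockout. In hypoxia response NDRG1 rose by 0.81 ± 0.14 and 1.11 ± 0.14 and LOX, lysyl oxidase, by 1.35 ± 0.26 and 1.34 ± 0.26, with 3 of 18 members higher and 1 lower in the ELP1 and 2 higher in the CTU2 knockout. ACTA2, smooth muscle actin, fell by 2.45 ± 0.27 in the ELP1 knockout and changed by -1.18 ± 0.24 in the CTU2 knockout, a tested difference of -1.27 ± 0.29 (adjusted p = 0.00679), with 3 of 9 fibroblast and mesenchymal markers lower and 1 higher in the former and 2 lower in the latter. CCNE1 changed by -1.24 ± 0.17 in the ELP1 knockout, where replication and S phase had 3 of 24 lower, a median of -0.14 and an adjusted p of 0.0755, and by -0.99 ± 0.17 in the CTU2 knockout, where that list was called lower (adjusted p = 0.0167; adjusted p = 0.0751 with an estimated correlation).

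None of the following 5 lists was called in either knockout (camera adjusted p from 0.108 to 0.902), while single members were. These lists cover tRNA modification, m6A, mRNA decay, ribosome quality control and endoplasmic reticulum chaperones with the unfolded protein response. Of 19 genes of mcm5s2U tRNA modification 1, URM1 (-0.52 ± 0.15), was lower in the ELP1 and 1, CTU2 itself, in the CTU2 knockout, with medians of -0.14 and 0.02. Of 24 m6A writers, readers and erasers 1 was higher in the ELP1 knockout, the reader IGF2BP2 (0.44 ± 0.11), and 0 were called in the CTU2 knockout, with medians of -0.01 and -0.12. Of 47 genes of mRNA deadenylation, decapping and exonucleases 4 were lower in the ELP1 knockout, among them the exosome subunit EXOSC2 (-0.58 ± 0.13), and 1 in the CTU2 knockout. Of 25 genes of ribosome collision and quality control 1, USP10 (-0.49 ± 0.11), was lower in the ELP1 knockout and 2 were higher in the CTU2 knockout. No gene of 25 endoplasmic reticulum chaperones and unfolded protein response was called in the ELP1 knockout, and 2 were higher in the CTU2 knockout, among them HERPUD1 (0.67 ± 0.15).

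Intronic reads, which come mostly from unspliced RNA, moved with the exonic changes for several genes. Intronic PCSK2 was higher in the ELP1 knockout by 3.97 ± 0.57 (edgeR adjusted p = 6.57e-05), intronic NRXN3 changed by -3.41 ± 0.26 in the CTU2 knockout (2.48e-10) and intronic ASNS by 1.10 ± 0.23 (0.00921). Of genes called higher in the ELP1 knockout 324 of 368 with intronic reads had the same sign there, and of lower genes 337 of 404. From intronic reads edgeR called 66 and 30 of them the same way and 0 the opposite way. In the CTU2 knockout the same sign was seen in 234 of 279 and 161 of 200, with 29 and 10 called the same way and 0 the opposite way. Intronic and exonic reads come from the same libraries, so their signs are not independent. Cytosolic aminoacyl-tRNA synthetases had higher intronic reads in the CTU2 knockout in 19 of 20 members, by a median of 0.20 (camera adjusted p = 0.000132; adjusted p = 0.00730 with an estimated correlation).

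Other divisions of the libraries into groups of the same sizes were fitted to see whether chance could give as many calls. For abundance 1 of 100 splits, the real one, gave as many calls in each comparison. For ELP1 against WT it gave 1315 (highest other 1) and for CTU2 against WT 897 (highest other 38). For ELP1 against CTU2 it gave 1013 (highest other 1). Every other split mixes the genotypes, so their differences enter its spread and few calls are likely. Labelling times were not kept balanced in these splits. The splits cannot tell an effect of genotype from a chance difference between cultures or clones. For turnover, counted at an unadjusted p under 0.05, 1 of 35 splits reached the real 502 for CTU2 against WT (highest other 439), which is the smallest share that 35 splits can give, and limma called 0 genes there. Chance was not excluded for ELP1 against WT, where 2 of 35 reached 514 (highest other 545), nor for ELP1 against CTU2, where 4 of 35 reached 419 (highest other 440). For new RNA it was not excluded for ELP1 against WT (362, reached by 4 of 35 splits, highest other 1954) nor for CTU2 against WT (311, reached by 18 of 35, highest other 1627). The 35 splits do not keep labelling times balanced, and the 18 that do are too few for a share under 0.05. Among these 18 the highest other counts for turnover were 362, 423 and 434 for ELP1 against WT, CTU2 against WT and ELP1 against CTU2, and for new RNA 311 and 1627 for ELP1 and CTU2 against WT. The 1954 for new RNA and the 545 for turnover of ELP1 against WT came from the same split. It put the 1 h libraries against the 2 h libraries. Labelling time was a factor in these fits, set there by the CTU2 knockout libraries alone. The contrast thus sets the change from 1 h to 2 h in ELP1 knockout and WT libraries against that in the CTU2 knockout. For CTU2 against WT the split by labelling time gave 288 for new RNA and 323 for turnover. The 1627 came from the split of CTU2 1 h and WT 2 h libraries against WT 1 h and CTU2 2 h libraries. That split follows a genotype difference of opposite sign at the 2 times (medians of 0.378 at 1 h and -0.377 at 2 h). Its 1627 genes were counted at an unadjusted p under 0.05, and calls at an adjusted p were not counted for it.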
